A study of Homo sapiens with 6 samples.

How the data were processed

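RNA was taken from A549 cells 48 h after transfection with 20 nM siRNA by Lipofectamine RNAiMAX, and sequenced on a BGISEQ-500, per the labels' protocols and design text. There were 3 libraries with CDK5 siRNA and 3 with scramble siRNA, grouped by their titles. The labels name 3 CDK5 siRNAs and an equal pool of them. Which of these each library received, the scramble sequence, the RNA selection and the strandedness of the libraries are not given in the sources used here.

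The deposited table holds expected counts (estimated reads per gene, not whole numbers and not normalized) and FPKM per library, per the file headers and the design text. The submitters' processing notes name Trimmomatic, Bowtie2 and RSEM without versions, and give mm8, a mouse build, as the genome, although the samples are human. The identifiers of the table are human NCBI Gene numbers, so that field was not used. RSEM divides reads that match several transcripts among them by estimate, so values of near-identical or overlapping genes are less certain. The authors' FPKM divides by transcript length and by the library's total, so a feature that takes many counts lowers all others.

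The table has 26366 rows, 22815 with an NCBI Gene number, of which 22171 matched the RefSeq gene table used for names, and 3551 features named only by the sequencing provider. All have a gene name or feature identifier and entered the total counts, while the library sizes of the main test were summed over the 17419 tested rows. A single unnamed feature took 10.5% to 11.3% of the counts of a library, and the provider's features together 12.5% to 13.3%. The authors' group means were not used. The total count was 21615958 to 21966840 per library. Replicates differed by more than sampling noise (chi-square per degree of freedom of 4.26 to 7.11 over genes with a mean count of at least 50), which does not show that they came from separate cultures; each was entered as a sample.

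Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with defaults, TMM factors, glmQLFit and glmQLFTest on all 6 libraries without covariates, and Benjamini-Hochberg adjustment over 17419 rows. TMM factors were 1.05 to 1.06 for CDK5 siRNA and 0.939 to 0.952 for scramble libraries. Standard errors of log2 fold changes are the fitted coefficient over the root of its F statistic. A gene was called at an adjusted p under 0.05, and with the submitters' threshold also at a fold change over 2. CPM values use the TMM-scaled library sizes.

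Of 35 gene lists, 34 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, on voom values), with Benjamini-Hochberg adjustment over the lists. The lists, the tests and the alternatives, except where stated, were fixed before the data were examined. Named genes are CDK5, WWTR1 and YAP1. They further include the 10 largest rises and 10 largest falls among genes with a symbol that passed both thresholds, with all CDK5 siRNA libraries on one side of all scramble libraries and a mean of at least 1 FPKM in the higher group, passing over LOC, pseudogene and read-through symbols. From each list come up to 4 members with the smallest adjusted p, or up to 2 with the highest level where no member passes. Genes named outside that rule are said to be so, or are the few members that moved against their list. Some genes, and 1 of the lists that passed camera, are not reported here.

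Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter or a filter of 1 CPM in 3 libraries, limma with trend on log2(FPKM + 1) with pseudocounts of 0.1 and 0.01, filters and quantile normalization, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Library totals alone, and removal of each library's trend on GC content and transcript length (loess, span 0.3), were added after the data were seen. GC content, length and 3' UTRs came from the longest coding transcript per gene in GENCODE 29 (GRCh38), which gave a value for 14885 tested rows, 90.9% of those with an NCBI Gene number. The siRNA sequences were matched to the same transcripts.

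For 13512 tested genes with a 3' UTR of at least 50 bases, each 7-base word carried by at least 100 genes was ranked by the mean log2 fold change of its carriers against the rest, after regression on 3' UTR length and GC content, transcript length and GC content, and level (Python 3.11.15, SciPy 1.17.1). The edgeR, DESeq2, limma-voom and preset-correlation camera tests and the word ranking were tested on simulated data. For the comparison of CDK5 with scramble siRNA, edgeR recovered 70% of 50 genes changed by 1 on the log2 scale and 88% of 50 changed by 2, and called 10 of 17219 unchanged genes. Only 200 simulated genes were changed, far fewer than were called in the real data, so these rates need not apply there. Camera called the shifted list and 0 of 19 random lists. Simulated genes were drawn independently, so this does not test lists of correlated genes, such as the ribosomal protein list (estimated correlation 0.692). Genes of the shifted list under 1 CPM were raised by more than the set shift. A shift of 0.1 put 10 of 10 drawn words in the lowest 1%, and no shift 0 of 10.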

Results

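The study measured gene expression by RNA-seq in A549 cells, a human lung adenocarcinoma line, after transfection with small interfering RNAs (siRNAs) against CDK5 or with a scramble siRNA. CDK5 is a serine/threonine kinase best known from neurons, and the series title sets it beside TAZ, the transcriptional co-activator of the Hippo pathway that the gene WWTR1 encodes. Each group held 3 libraries, made 48 h after transfection with 20 nM siRNA. The libraries were close in depth, with 21870856, 21803493 and 21768519 expected counts after CDK5 siRNA and 21966840, 21615958 and 21947941 after scramble siRNA. At this depth 23232 to 23434 rows had a count above 0 after CDK5 siRNA and 22672 to 22787 after scramble siRNA. At 1 FPKM or more there were 13233 to 13242 and 12588 to 12695. Whether fold changes follow a gene's level was not tested. The scalings tried shift all genes nearly alike and do not address it. The labels number the libraries 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Log2 CPM, each gene's count scaled to the depth of its library, correlated at a mean of 0.993 between libraries of the same group and 0.970 between libraries of different groups, across genes, which are not independent replicates.

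CDK5 mRNA fell to 6.74% of its scramble level. CDK5 (NCBI Gene 1020) stood at 1.90, 1.81 and 1.79 CPM in the libraries labelled CDK5 siRNA and at 28.6, 24.9 and 28.3 CPM in the scramble libraries. The group means were 1.83 ± 0.0586 and 27.3 ± 2.04 CPM (SD, n = 3 each), a log2 fold change of −3.89 ± 0.10 (SE; edgeR quasi-likelihood test, adjusted p = 3.0e-08). In the deposited FPKM values the means were 0.907 ± 0.0306 and 20.96 ± 1.55 (SD, n = 3 each). The gene lies on the minus strand of chromosome 7 at 151053812 to 151058530 of GRCh38. The labels list 3 CDK5 siRNAs and a pool, without saying which of them each library received. All 3 target sequences matched the coding sequence of CDK5 transcript ENST00000485972.5, which has 12 exons. GUCGAUGACCAGUUGAAGA lies in exon 9 at 151055037 to 151055055, CCACAACAUCCCUGGUGAA in exon 11 at 151054255 to 151054273, and GCAGAACCUUCUGAAGUGU spans the junction of exons 11 and 12, between 151054081 and 151054215. The first and the second also matched the processed pseudogene CDK5P1 on chromosome 8, which has no row in the table.

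WWTR1 was lower and its paralog YAP1 higher after CDK5 siRNA. WWTR1 (NCBI Gene 25937, chromosome 3, 149517235 to 149736714, minus strand) fell from 385 ± 17.7 to 143 ± 6.15 CPM (SD, n = 3 each), a 2.69-fold drop with a log2 fold change of −1.43 ± 0.05 (SE; edgeR adjusted p = 7.8e-08). YAP1 (NCBI Gene 10413, chromosome 11, 102110461 to 102233423, plus strand) rose from 140 ± 5.07 to 198 ± 4.75 CPM (SD, n = 3 each), with a log2 fold change of 0.50 ± 0.04 (SE; edgeR adjusted p = 8.1e-06). For both genes every CDK5 siRNA library lay outside the range of the scramble libraries. The WWTR1 3' UTR of 3570 bases holds 0 matches to bases 2 to 8 of the 3 siRNA guide strands and 1 match to bases 2 to 7 of the third followed by A. The similarly named gene TAZ (tafazzin) is a different gene.

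**Figure D1:**
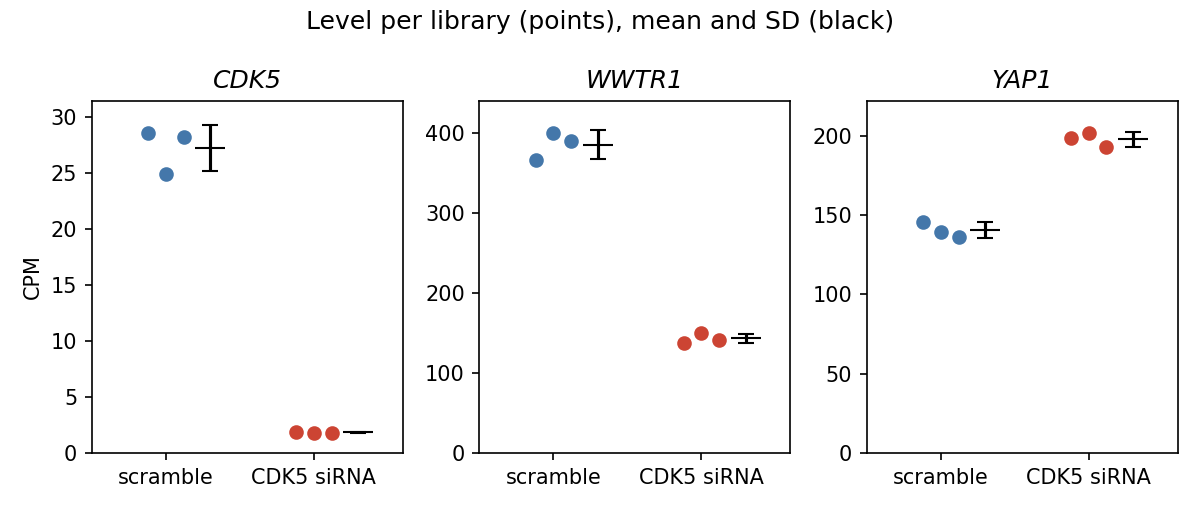
CPM (y axes, from 0) of CDK5, WWTR1 and YAP1 in each of the 3 scramble (blue) and 3 CDK5 siRNA (red) libraries, with group mean and SD in black. CDK5 fell from 27.3 to 1.83, WWTR1 fell from 385 to 143 and YAP1 rose from 140 to 198.

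The Hippo pathway and its reported targets moved in both directions. Of 28 tested core Hippo genes 7 rose, 14 fell and 7 did not pass the test, with the same counts when adjusted over the list alone. Beside WWTR1, the kinase LATS2, which phosphorylates YAP and TAZ, fell by 1.08 on the log2 scale (SE 0.07, as for each ± after a log2 fold change), while MAP4K4, a kinase upstream of LATS, rose by 0.97 ± 0.03 and the angiomotin-like gene AMOTL1 by 1.33 ± 0.05. Of 25 YAP/TAZ target genes 7 rose, 12 fell and 6 did not pass, again with the same counts adjusted over the list alone. CCDC80 rose 5.06-fold (19.2 ± 0.541 to 97.2 ± 4.09 CPM, SD, n = 3 each), the receptor kinase AXL 2.15-fold and TGFB2 1.65-fold. The widely used readouts CTGF, CYR61 and ANKRD1, singled out after their values were seen, fell by 0.58 ± 0.13, 0.38 ± 0.11 and 1.67 ± 0.23 on the log2 scale. Neither list stood apart from other genes by camera (adjusted p = 0.239 for the core and 0.712 for the targets). The list medians were −0.15 for both, turned to 0.02 for both with library totals alone, and the mean of the targets was 0.03, opposite in sign to their median.

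More than 50% of the tested genes differed between the groups. With edgeR's quasi-likelihood test, 9892 of 17419 genes and features (56.8%) had an adjusted p under 0.05, of which 4844 were higher and 5048 lower after CDK5 siRNA. The submitters' threshold adds a fold change over 2, and 1907 passed both, 1326 higher and 581 lower. The 3 groups of points in the plot of all tested genes show these calls against level. The share of calls that were higher depended on the scaling: it was 49.0% with TMM factors and 66.8% with library totals alone, and among genes past both thresholds 69.5% and 84.2%. Limma on log2(FPKM + 1), which changed the measure, filter and test as well, gave 63.3%, and 48.3% after quantile normalization. Library totals alone moved the median of all genes up by 0.17 on the log2 scale, so gene group medians are also given there where they change sign. The spread between libraries of a group was small, with a biological coefficient of variation of 7.55%.

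**Figure D2:**
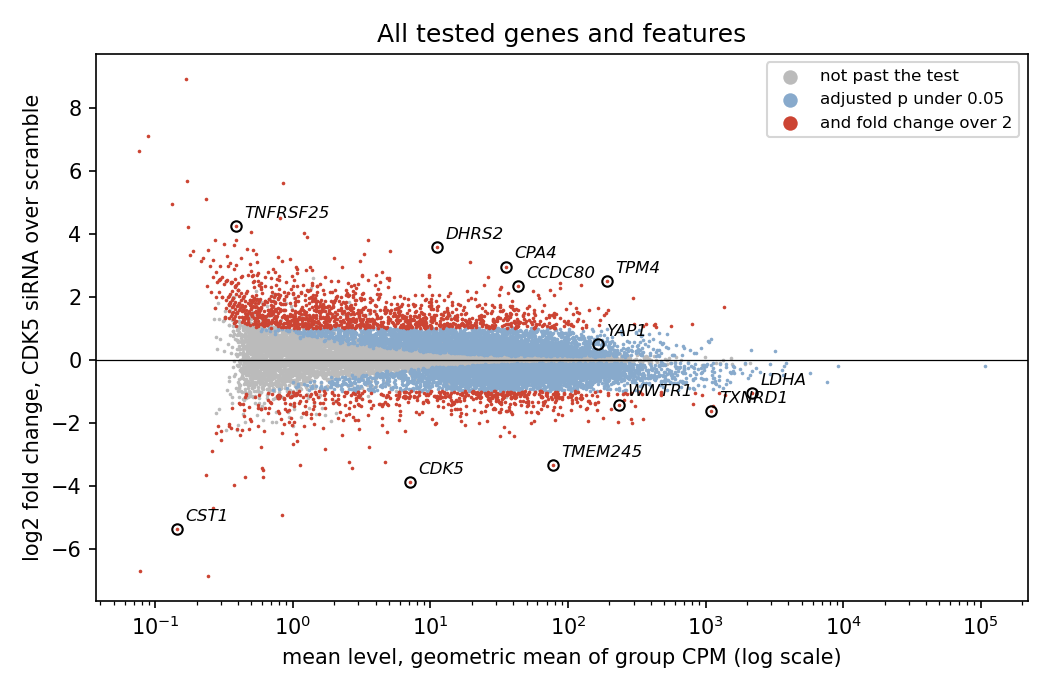
Log2 fold change (y axis, CDK5 siRNA over scramble) against mean level (x axis, geometric mean of the group CPM, log scale) for all 17419 tested genes and features, coloured by whether they passed the edgeR test and a fold change over 2. CDK5 (−3.89), WWTR1 (−1.43) and TMEM245 (−3.34) lie far below 0, and CPA4 (2.95) and TPM4 (2.50) far above.

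The genes with the largest rises were mostly low in scramble cells. The death receptor gene TNFRSF25 rose from 0.0813 ± 0.0742 to 1.63 ± 0.329 CPM and the thyroid hormone deiodinase gene DIO2 from 0.939 ± 0.0999 to 13.2 ± 1.05 CPM (SD, n = 3 each, here and below). The log2 fold change of TNFRSF25 went from 4.24 to 4.90 without scramble replicate 1 and to 3.68 without scramble replicate 3. DHRS2, a short-chain dehydrogenase, rose 11.8-fold to 38.4 ± 2.48 CPM, C1orf116 11.02-fold to 17.0 ± 1.17 CPM, TRIML2 8.65-fold to 56.9 ± 1.77 CPM and the carboxypeptidase gene CPA4 7.72-fold to 98.7 ± 2.82 CPM. The proteoglycan gene LUM rose 10.2-fold, the sarcomeric gene MYPN 9.30-fold, FAM9B 8.75-fold and the hyaluronan synthase gene HAS2 8.74-fold. Adjusted p-values of these 10 ranged from 3.8e-08 for CPA4 to 1.9e-04 for TNFRSF25.

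Beside CDK5, the membrane protein gene TMEM245 was the only 1 of the 10 largest falls that was abundant in scramble cells, dropping from 249 ± 7.83 to 24.6 ± 1.52 CPM (log2 fold change −3.34 ± 0.05, edgeR adjusted p = 4.8e-09). ADGRF3, an adhesion G protein-coupled receptor, fell from 14.6 ± 1.70 to 1.51 ± 0.828 CPM, the S-phase cyclin gene CCNE2 from 9.33 ± 1.18 to 1.37 ± 0.423 CPM, HASPIN, a mitotic histone H3 kinase, from 8.80 ± 1.51 to 0.808 ± 0.923 CPM and the cytochrome P450 gene CYP4F11 from 7.80 ± 0.630 to 0.822 ± 0.236 CPM. CEP295NL, GCKR and IGFLR1 fell to 0.159 ± 0.0670, 0.173 ± 0.0742 and 0.115 ± 0.199 CPM from 2.19 ± 0.254, 2.02 ± 0.600 and 1.58 ± 0.575 CPM. The HASPIN values after CDK5 siRNA were uneven (1.81, 0 and 0.611 CPM). Its log2 fold change of −3.43 went to −4.83 without CDK5 siRNA replicate 1 and to −2.85 without CDK5 siRNA replicate 2. IGFLR1 had no counts after CDK5 siRNA outside replicate 1, so its log2 fold change of −3.71 rests on that library and went to −8.10 without it. Without CDK5 siRNA replicates 2 and 3 it was −3.15 and −3.16. The cystatin gene CST1 had 1 count over the CDK5 siRNA libraries and 52 over the scramble libraries. The depth-scaled ratio was 58.3, with a 95% exact interval of 10.0 to 2346, which covers counting error only. The log2 fold change of CST1 went from −5.39 to −7.19 without CDK5 siRNA replicate 2, which held that count. Without CDK5 siRNA replicate 1 or 3 it was −4.95.

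Genes of DNA replication, mitosis and homologous recombination fell together. Of 26 G1/S and replication genes 23 fell and 0 rose (median log2 fold change −0.83), among them the licensing factor CDT1 (−1.07 ± 0.05, SE) and the flap endonuclease FEN1 (−1.31 ± 0.07). Of 29 G2/M genes 27 fell and 0 rose (median −0.79), including CDC20 (159 ± 8.98 to 70.2 ± 1.77 CPM), CDK1 (136 ± 6.41 to 64.1 ± 2.19 CPM) and cyclin B1, CCNB1 (198 ± 12.2 to 91.5 ± 1.64 CPM). Of 23 homologous recombination genes 19 fell and 2 rose (median −0.47), with FANCA at −1.09 ± 0.05 and the helicase gene BLM at −1.04 ± 0.09, while RAD50 and RAD52, named because they were the only 2 that rose, stood at 0.31 ± 0.04 and 0.37 ± 0.08. Of 21 DNA damage checkpoint genes 13 fell and 2 rose (median −0.34), and the checkpoint kinase CHEK1 dropped 3.09-fold, from 62.8 ± 2.64 to 20.3 ± 0.978 CPM. All these counts were the same adjusted over the list alone. The medians kept their sign under the 4 scalings tried, but these moved the median of all genes by at most 0.17. Medians this far from 0 could hardly have changed sign. Camera placed the 4 lists below other genes with a preset correlation of 0.01 (adjusted p = 8.8e-10, 2.2e-11, 1.1e-04 and 0.0105). With an estimated correlation the adjusted p was 0.424 for G1/S and G2/M, 0.437 for homologous recombination and 0.456 for the checkpoint list, so none of the 4 passed. That variant takes its degrees of freedom from 6 libraries, so it had little power here. Failing it does not show that correlation between genes accounts for the preset result, and leaves that open. Of 15 non-homologous end joining genes 3 rose and 9 fell, including RIF1 (−1.19 ± 0.05), and that list did not pass camera (adjusted p = 0.0794).

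Ribosomal protein, NRF2 target and glycolytic genes were lower as well. Of 30 ribosomal protein genes 27 fell and 0 rose (median −0.53), each by less than 2-fold, with RPL32 falling from 824 ± 34.7 to 511 ± 9.99 CPM. This list was fixed among those kept to watch RNA quality, and the RNA selection is not given. The fall of the ribosomal protein genes is therefore not assigned to expression. Of 25 targets of NRF2, the regulator of the antioxidant response, 20 fell and 2 rose (median −0.56). The thioredoxin reductase gene TXNRD1 fell 3.13-fold, from 1949 ± 60.5 to 623 ± 20.6 CPM, the aldo-keto reductase gene AKR1B10 2.18-fold and GCLC, of glutathione synthesis, 2.40-fold, whereas ME1 and ABCC3, the only 2 that rose, stood at 0.52 ± 0.04 and 0.86 ± 0.08. Of 24 hypoxia and glycolysis genes 22 fell and 1 rose (median −0.73), or 23 and 1 adjusted over the list alone. Lactate dehydrogenase A, LDHA, fell from 3160 ± 72.6 to 1514 ± 61.4 CPM and GPI, of glycolysis, from 1387 ± 48.9 to 641 ± 27.9 CPM, and the gene that rose was VEGFA (0.86 ± 0.06). The counts of the ribosomal protein and NRF2 lists were the same adjusted over the list alone. The medians of all 3 kept their sign under the 4 scalings, whose shifts were too small to turn them. Camera gave adjusted p = 3.6e-11, 4.3e-07 and 4.1e-08 for the 3 lists, and adjusted p = 0.424 for each with an estimated correlation.

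Interferon response genes and replication-dependent histone genes were higher. Of 25 interferon response genes 16 rose and 1 fell (median 0.71), or 18 and 1 adjusted over the list alone. OAS1, a sensor of double-stranded RNA, rose from 26.7 ± 0.523 to 61.4 ± 0.540 CPM and IFI44 from 12.2 ± 0.546 to 39.5 ± 2.56 CPM. Of 8 tested replication-dependent histone genes 5 rose and 0 fell (median 1.04), with H2BC5 (listed as HIST1H2BD) at 1.97 ± 0.13. The histone list, like the ribosomal protein and immediate early lists, was fixed among those kept to watch RNA quality. The RNA selection of the libraries is not given, so the rise of these genes is not assigned to expression. The histone counts were the same adjusted over the list alone. Both medians kept their sign under the 4 scalings, whose shifts were too small to turn them. Camera gave adjusted p = 2.9e-04 and 0.0363, and adjusted p = 0.424 for each with an estimated correlation. Without scramble replicate 2, or with the replicate number as a block, the histone list no longer passed (adjusted p = 0.0814 and 0.0557).

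**Figure D3:**
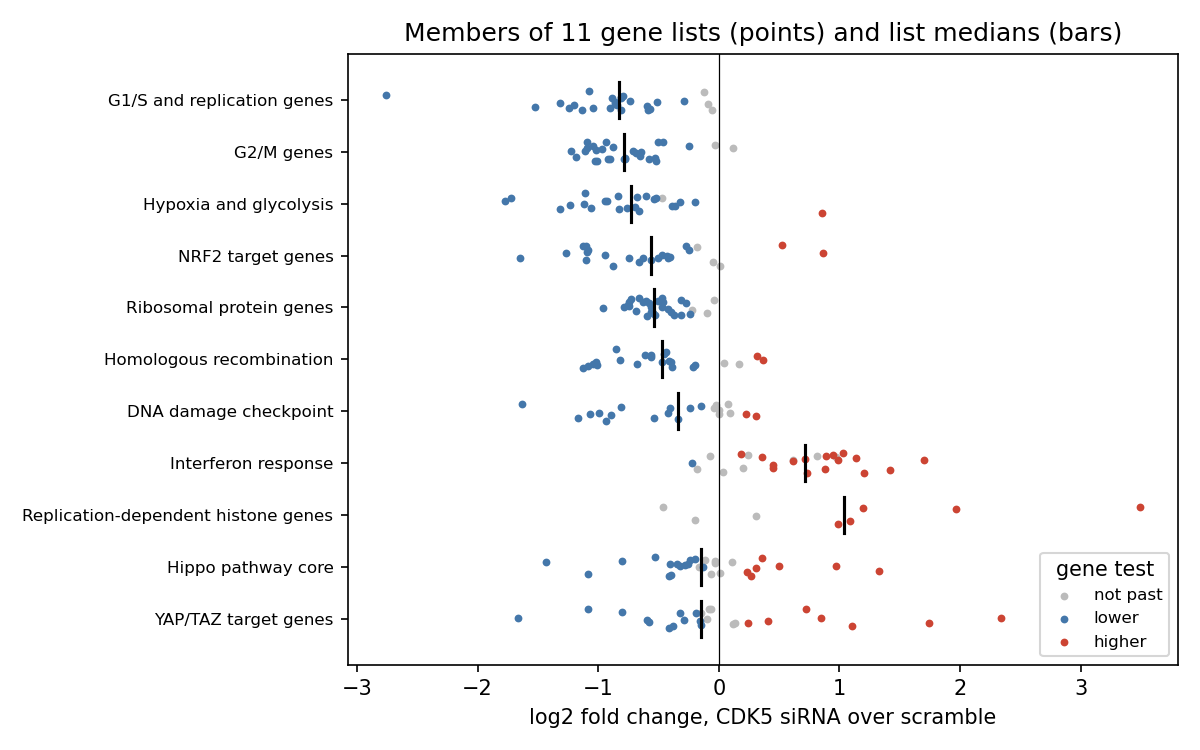
Log2 fold change (x axis, CDK5 siRNA over scramble) of the tested members (points) of 11 gene lists (y axis), coloured by the edgeR gene test, with each list's median as a black bar. The upper 9 lists passed camera with the preset correlation (0 with an estimated one), from G1/S and replication genes (median −0.83) to replication-dependent histone genes (median 1.04), and the Hippo core and YAP/TAZ targets, with members on both sides of 0, did not; their medians of −0.15 turn to 0.02 with library totals alone.

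The remaining lists reported here did not pass camera, though many of their members passed the gene test; unless stated, these counts were the same adjusted over the list alone. Of 11 CDK5 partners and activators 2 rose and 5 fell, with cyclin D1, CCND1, falling from 1329 ± 81.0 to 499 ± 5.62 CPM and CABLES1 rising by 1.12 ± 0.07. Of 18 other CDK genes 6 rose and 7 fell, with CDK16 at 1.45 ± 0.04 and CDK9 at 0.97 ± 0.06. Of 7 tested neighbours of CDK5 on chromosome 7, 1 rose and 2 fell, and none fell as CDK5 did (SLC4A2 −0.34 ± 0.04, AGAP3 −0.39 ± 0.06, ASIC3 2.00 ± 0.23). Of 26 actin, adhesion and migration genes 15 rose and 9 fell (median 0.21, adjusted p = 0.0794), and the tropomyosin gene TPM4 rose from 80.3 ± 4.41 to 453 ± 15.7 CPM. Of 18 mesenchymal markers 10 rose and 3 fell, with ACTA2 at 2.03 ± 0.08 and COL1A1 at −1.57 ± 0.08, and of 18 epithelial markers 4 rose and 3 fell, with KRT7 at −0.66 ± 0.04. Of 21 TGF-beta response genes 12 rose and 6 fell, with ID2 at −1.43 ± 0.08 and TGFBR2 at 0.82 ± 0.06. Of 22 NF-kB and inflammatory genes 11 rose and 4 fell, with PTGS2 at 2.63 ± 0.19 and CCL2 at −2.01 ± 0.15, and of 18 immediate early genes 7 rose and 6 fell, with KLF2 at 2.38 ± 0.08.

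Among stress and metabolic lists, 3 of 18 unfolded protein response genes rose and 8 fell, and 7 of 21 ATF4 targets rose and 9 fell, with NUPR1 at 1.94 ± 0.09 and SLC7A5 at −0.75 ± 0.05. Of 23 cholesterol synthesis genes 7 rose and 9 fell, or 7 and 10 adjusted over the list alone. Of 11 fatty acid synthesis genes 4 rose and 6 fell, with ACLY at −0.40 ± 0.03. Of 22 respiratory chain genes 4 rose and 10 fell, with ATP5F1B at −0.49 ± 0.03. Of 22 apoptosis regulators 7 rose and 10 fell, with MCL1 at −0.98 ± 0.04, and of 23 lysosome and autophagy genes 6 rose and 10 fell, with SQSTM1 at −0.89 ± 0.05. Of 13 RNA interference genes 2 rose and 8 fell, with AGO2 at −1.02 ± 0.06 and DICER1 at −0.70 ± 0.04 (camera adjusted p = 0.0514, which went to 0.0442, 0.0385 and 0.0471 without CDK5 siRNA replicate 1, replicate 2 and scramble replicate 2). Of 15 housekeeping genes 3 rose and 9 fell, with GAPDH at −0.70 ± 0.04 and HPRT1 at −1.47 ± 0.04 (adjusted p = 0.0806, and 0.0494 without CDK5 siRNA replicate 3). Medians turned from below to above 0 with library totals alone for the CDK5 partners, other CDKs, CDK5 neighbours, unfolded protein response, ATF4, cholesterol, respiratory chain, apoptosis and lysosome lists, and with upper-quartile factors too for the other CDKs, the neighbours, ATF4, cholesterol and lysosome. Medians and means differed in sign for the other CDKs, the neighbours and the ATF4 targets.

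Few markers of other cell types were tested. Of 15 haematopoietic markers 6 were tested, and ITGAM was higher over all genes (0.38 ± 0.14) and not when adjusted over the list alone, which left 0 past the test. Of 13 fibroblast and endothelial markers 6 were tested, 2 rose (LUM and DCN) and 1 fell (COL1A1), both rising genes from under 1.1 CPM. Of 20 lung lineage markers 5 were tested and 4 rose, with the surfactant lipid transporter ABCA3 at 0.75 ± 0.06 (84.7 ± 5.38 against 50.3 ± 2.64 CPM). The last 2 counts were the same adjusted over the list alone. None of the 13 mitochondrially encoded genes has a row in the table.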

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

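Library totals alone, the removal of GC and length trends and the test of scaling on the ribosomal protein median were chosen after the data were seen. CDK5 and WWTR1 stayed lower and past the threshold under every alternative run, with log2 fold changes of −4.51 to −3.52 and −1.48 to −1.22. The number of genes with an adjusted p under 0.05 ran from 8132 to 10098, with 8775 by DESeq2 and 9995 by limma-voom, and from 9015 to 9666 with a library left out. The calls by DESeq2 included 8667 of the 9892. The number of higher genes shifted most with library totals alone, from 4844 to 6743. For lower genes and genes past a fold change over 2, the largest shifts came with limma on FPKM. Lower genes numbered 3042 with log2(FPKM + 1), 3022 and 3024 with pseudocounts of 0.1 and 0.01, 2918 without a filter and 3092 with a filter of 0.1 FPKM. Genes past a fold change over 2 numbered 694 (543 higher, 151 lower) with log2(FPKM + 1), 693 (540 and 153) without a filter, 704 (549 and 155) with a filter of 0.1 and 616 (356 and 260) after quantile normalization, and 265 and 284 were lower with the smaller pseudocounts. A pseudocount of 1 by its construction shrinks folds of low genes. Quantile normalization of the same values brought lower genes to 4208. It gives all libraries the same distribution, which by itself tends to balance the directions. It therefore does not show how much of the shift in direction is due to scaling. Library totals alone left 3355 lower, 350 of them by over 2-fold. With GC and length trends removed, 95.2% of the 9164 called genes with a transcript were still called, and the ribosomal protein median moved from −0.53 to −0.59, which argues against those trends as the whole of either. That median stayed below 0 under the 4 scalings, at −0.37 with library totals alone. These scalings moved the median of all genes by at most 0.17 from TMM, so none could have brought −0.53 to 0. The sign does not depend on the choice among these 4, and no further conclusion on scaling is drawn. With an estimated correlation 0 lists passed, and with fry, which does not compare a list with other genes, 24 did. The actin list had an estimated correlation of 0.00969, near the preset 0.01, and still went from a camera adjusted p of 0.0794 to 0.424. The NRF2 list, at 0.0523, went from 4.3e-07 to 0.424. The few degrees of freedom of that variant thus limited it for such lists as well. Named genes kept their direction and an adjusted p under 0.05 under the alternatives run on them. With log2(FPKM + 1) some of the largest rises and falls no longer passed a fold change over 2. MYPN went from 3.22 to 0.93 on the log2 scale and, without a filter, CEP295NL from −3.74 to −0.90. The 6 libraries can be split into only 10 pairs of groups of 3, too few for a share under 0.05; the real split gave 9892 genes and the highest other 1. In simulated data with only 200 changed genes, 22% of genes changed by 0.3 on the log2 scale were recovered, a rate that need not apply to the real data.

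The replicate block gave 9650 genes, and CDK5 and WWTR1 at −3.89 and −1.43. Same-numbered libraries correlated in their deviations at 0.033, 0.035 and 0.011, too little to pair them, though each correlated best with its own number, a hint from the data and not the design. The histone list had an adjusted p of 0.0557 with the block, and no other list changed its call.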

Other observations

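The test of a seed match in WWTR1 was chosen only after the result was seen, as were the 18 families of genes, taken from their symbols, the genes named from them, the GGAGA words with the tests on them, the exact interval on 47.5%, the count of 6-base words, and the search for GAAGTGA and the site contrast on the guide words, which each turned a result against a seed explanation, by the bound first written, into an open one. By camera 10 of the 18 families passed, and 0 with an estimated correlation, a variant with little power on these few libraries. Of 39 proteasome subunit genes 33 were lower after CDK5 siRNA and 2 higher (median log2 fold change −0.37, camera adjusted p = 7.0e-08), with PSMA3 falling from 165 ± 4.41 to 82.9 ± 1.04 CPM (SD, n = 3 each). Of 45 splicing factor genes 31 were lower and 3 higher, including SNRPB (359 ± 6.61 to 185 ± 11.9 CPM). Of 42 genes with symbols like those of ribosome biogenesis and RNA polymerase I genes, 29 were lower and 2 higher. The lowest was NOL3 and the highest NOL4, and a symbol alone does not show that a member acts there. Of 52 translation initiation factor genes 35 were lower and 8 higher, with EIF4G2 at −1.07 ± 0.04 (SE) and EIF3F at 0.97 ± 0.04, and 7 of the 9 chaperonin subunit genes were lower, with CCT4 at −1.02 ± 0.04. Camera gave adjusted p = 4.5e-06, 5.3e-06, 3.2e-05 and 0.00971 for these 4, and with an estimated correlation the adjusted p was 0.337 for the proteasome and 0.395, 0.437, 0.284 and 0.466 for the 4. Their medians kept their sign under the 4 scalings, as shifts of at most 0.17 from TMM could hardly turn them. The median of 78 mitochondrial ribosomal protein genes (9 higher, 35 lower) turned from −0.13 to 0.04 with library totals alone.

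Of 32 collagen genes 17 were higher and 4 lower (median 0.61, camera adjusted p = 0.00268, and adjusted p = 0.284 with an estimated correlation). COL5A2 rose from 69.3 ± 4.12 to 197 ± 5.45 CPM and COL4A6 from 20.6 ± 1.48 to 74.2 ± 0.648 CPM (SD, n = 3 each), while COL1A1 fell. Of 257 long intergenic non-coding genes 73 were higher and 11 lower (median 0.32, camera adjusted p = 0.00242, and adjusted p = 0.236 with an estimated correlation). Of all 17419 tested rows 4844 were higher and 5048 lower. The share of non-coding genes called higher was thus near that of all rows, and the share called lower was far under it. Of 414 genes named ZNF 147 were higher and 70 lower (median 0.15, camera adjusted p = 0.0200, and adjusted p = 0.284 with an estimated correlation), and of 47 ubiquitin specific protease genes 10 were higher and 22 lower (median −0.17, adjusted p = 0.0204, and 0.337 with an estimated correlation). The RNA polymerase III and cytochrome P450 families did not pass (adjusted p = 0.189 and 0.309), but single members moved far: POLR3G fell 4.95-fold, from 82.9 ± 4.17 to 16.7 ± 1.98 CPM, and its paralog POLR3GL rose 2.74-fold, from 7.25 ± 0.166 to 19.9 ± 0.884 CPM. The xenobiotic enzyme gene CYP1B1 rose 5.18-fold, from 54.9 ± 6.44 to 284 ± 14 CPM. The medians of the collagen, non-coding and ZNF genes kept their sign under the 4 scalings. That could hardly be otherwise, since upper-quartile factors and library totals move all genes upward. The median of the protease genes shrank to −0.0079 with library totals alone.

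An siRNA can lower transcripts other than its target by pairing of guide bases 2 to 8, the seed, with the 3' UTR. All 3 of the guide seed words lay in the lowest 1% of 15982 7-base words ranked by the fold change of their carriers. TGAAGTG ranked 1 (2179 carriers, −0.09 ± 0.01 on the log2 scale against other genes, SE), CTGGTGA ranked 2 (1843 carriers, −0.10 ± 0.02) and GTTGAAG ranked 24 (1481 carriers, −0.06 ± 0.02), while the passenger strand words ranked 343, 8421 and 11671. Off-target pairing by the guides may therefore account for part of the falls. Of 451 genes lower by over 2-fold with a searched 3' UTR, 47.5% carried a guide word (95% exact interval 42.8 to 52.2), against 31.4% of all 13512 genes and 27.2% of genes higher by over 2-fold, while of all 4546 lower genes 36.4% did. Unlike the ranking, these shares were not corrected for 3' UTR length or GC content, and longer 3' UTRs hold more words. Even a 6-base guide word was absent from the 3' UTR of 31.5% of the lower genes (95% exact interval 30.2 to 32.9; 35.5% of all genes), far over the 5% of false calls allowed, which argues against direct 3' UTR pairing as the whole of the falls. Sites elsewhere in a transcript (5.63% of lower genes had no such word in the whole transcript, 7.35% of all genes), indirect effects of off-target pairing and effects of CDK5 loss stay open, and the design does not separate them.

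The WWTR1 log2 fold change of −1.43 was −1.40 ± 0.04 (SE) with GC and length trends removed, which argues against those trends as the cause. Its 12 annotated transcripts hold 0 guide seed words of 7 bases. The 3' UTR does hold 2 copies of the 6-base word of the first guide (TTGAAG) and 2 of the third (GAAGTG). It also holds 1 copy of GAAGTGA, the match to bases 2 to 7 of the third guide followed by A. GAAGTGA ranked 3 of the 15982 words, and its 1905 carriers lay −0.10 ± 0.02 from other genes. The full seed word of that guide, TGAAGTG, with which it shares 6 bases, stood at −0.09 ± 0.01. A direct effect of an siRNA on WWTR1 and an effect of CDK5 loss cannot be told apart here, because CDK5 was lowered by siRNA in all libraries of the group and the labels do not say which siRNA each received. An effect by way of CDK5 stays open as a hypothesis, untested.

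At the other end of the ranking, 9 of the 10 highest words held GGAGA, and the highest 6-base word was CGGAGA (1251 carriers, 0.14 ± 0.02 above other genes). A candidate explanation is the seed of the scramble siRNA, whose targets would be lower in the scramble cells. Genes with 2 or more sites did not lie above genes with 1 (difference of 0.00 ± 0.05, z of −0.041). The same contrast for the 3 known guide words gave z of −1.10, −1.81 and −1.10. All 3 went in the direction of a seed, but none passed the bound set. By that bound the contrast would not have recognised these known seeds either, so it leaves the question open. Purine-rich 3' UTRs as such stay open too: the 116 words of A and G without GGAGA had a median z of 0.726 against 2.57 for the 12 with it, below the bound first set for this explanation, but GGAGA was picked from the top of the same ranking, so this contrast decides nothing. The scramble sequence is not given in the sources used here.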
